A study of Homo sapiens with 6 samples.

How the data were processed

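RNA was measured in SW480 cells, an established line derived from a human colorectal adenocarcinoma. Per the labels' protocols, cells were transfected with 30 pmol of siRNA against KHSRP or of a non-targeting scramble siRNA, with 2 µl of a lipid reagent, and total RNA was taken after 48 h. KHSRP encodes an RNA-binding protein with KH domains that is known for promoting the decay of transcripts with AU-rich elements and for a part in the maturation of some microRNA precursors. The RNA was amplified by whole-transcriptome amplification, labelled with biotin and hybridised to Affymetrix arrays. There were 6 arrays, 3 per siRNA, and the labels call the 3 of each group biological replicates.

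The authors deposited a table of log2 intensities with 70523 rows and 1 column per array. Per the submitters' processing notes, Affymetrix Expression Console, the RMA method and Transcriptome Analysis Console were used with genome build hg19, and versions and settings are not given in the sources used here. RMA corrects background, applies quantile normalization across arrays and summarises the probes of a set on the log2 scale, and it can compress the fold changes of dim genes. Array maxima of the deposited values ran from 19.72 to 19.93, higher than RMA alone is thought to give from scanner intensities. A further transform of the scale is therefore possible, and the sources used here do not describe one. The deposited log2 values were used as they stand. Array medians ran from 4.30 to 4.38, so no further scaling was applied for the main results. Arrays carry no count or depth, and the number of arrays limits the precision.

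Rows were named through the platform annotation supplied with the values, with symbols updated through a RefSeq gene table of assembly GRCh38.p14, from which no coordinates were taken because the builds differ. Of the rows, 25324 had an annotation and 45199 were unnamed here. Exactly 1 gene symbol stood on 23781 rows and several on 1543. Among rows with 1 symbol, 21497 matched the gene table by gene ID, 1974 by symbol and 306 by an older symbol, and 4 matched none and kept their annotated name. These rows held 22411 different genes. For the 528 genes with more than 1 row, the row with the highest mean over all 6 arrays was used. Rows with several symbols were left out, with 1 exception made for the siRNA target, whose row is annotated with KHSRP and with MIR3940, a microRNA gene. Without the exception the target would have had no value. Its addition gave 22412 tested genes.

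Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no intensity trend, not robust), as arrays labelled KHSRP siRNA minus arrays labelled scramble siRNA. Differences are log2 fold changes with limma's standard error (SE), and p-values were adjusted by the Benjamini-Hochberg method over all tested genes. A gene was called at an adjusted p under 0.05, and those with an absolute log2 fold change of at least 1 were also counted. All p-values are two-sided. KHSRP was also compared by an exact permutation test. No date, scan or batch was used here.

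The comparison, the lists and the alternatives were fixed before the data were examined. The 26 gene lists were: AU-rich-element transcripts described as KHSRP targets, inflammatory AU-rich-element transcripts, AU-rich-element binding and KH-domain proteins, mRNA decay and microRNA processing machinery, let-7 targets, G1/S and DNA replication, G2/M and mitosis, replication-dependent histones, p53 and CDK inhibitors, Wnt targets, colonocyte differentiation, mesenchymal transition, secreted factors, angiogenesis, matrix proteases and matrix, interferon-stimulated genes, integrated stress and unfolded protein responses, hypoxia and glycolysis, cholesterol biosynthesis, oxidative phosphorylation, cytosolic ribosomal proteins, splicing, lysosome and autophagy, apoptosis, markers of other cell types, and housekeeping genes. They held 644 members as written, of which 559, or 528 different genes, were measured. Of the 85 others, 43 stood on rows with several symbols. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera compares a list with all other genes. Camera with an estimated correlation and fry were alternatives.

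The genes named were fixed by rule. They were KHSRP, its paralogs FUBP1 and FUBP3, and the 12 protein-coding genes with the largest rise and the 12 with the largest fall among called genes whose groups did not overlap and whose higher mean lay above the median of all genes. Up to 3 called members per list followed, or the brightest members where fewer than 2 were called. Members that passed only when adjusted over the list alone, other metallothioneins, XPOT, aminoacyl-tRNA synthetase genes and small RNA genes were named after their values were seen.

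The alternatives were the replicate number as a block, quantile normalization again, centring on array medians, genes above the median level only, an intensity trend with a robust prior, array weights, the mean of a gene's rows, all rows of the table, an unmoderated linear model, other thresholds and leaving out each array. The inclusion of rows with several symbols of which 1 is a protein-coding gene, the block together with an estimated correlation, and a covariate for the 3 arrays with higher against the 3 with lower medians, were added after seeing the data. Tests of AU-rich elements and let-7 sites in 3' untranslated regions had been planned and were not run, since they need transcript sequences not used here. For 3 tests in the closing part, the bound needed to exclude or keep an explanation was made stricter after the values were seen. These were the comparison of KHSRP with olfactory receptor genes, the comparison of metallothionein pairs and the test of small RNA classes.

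The gene and list tests were tested on simulated data with the gene means of these arrays and limma's moderated variances, which are drawn toward a common value. The same comparison was made over 22412 genes, with 50 genes changed at each size. Of genes changed by 0.5 on the log2 scale, 18.0% were called, against 96.0% at 1 and 100% at 2 and at 3. Outside the planted genes 9 were called. The moderated variances spread less between genes than the arrays' own, so these shares do not hold for genes with a larger spread. In the real arrays MT1E, for example, was not called at 2.00 (SE 0.45, limma adjusted p = 0.0960). A list of 20 genes shifted by 0.3 gave a camera p of 1.02e-16 at the preset correlation and 8.21e-04 with an estimated one. The simulated genes were drawn independently, whereas the correlation estimated for real lists reached 0.547, in the cytosolic ribosomal protein list. So the simulation does not show how readily a real list of correlated genes would pass. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.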

Results

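Transcript levels were compared between SW480 colorectal adenocarcinoma cells transfected for 48 h with an siRNA against KHSRP and cells given a scramble siRNA, with 3 arrays per group. The comparison asks which transcripts differ when KHSRP, an RNA-binding protein known for promoting the decay of AU-rich-element transcripts, is targeted. Values are the deposited log2 intensities, which the submitters' notes ascribe to RMA, given as mean ± SD over 3 arrays. Pearson correlations over all rows ran from 0.987 to 0.991 between arrays of a group and from 0.984 to 0.988 between arrays of different groups.

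The KHSRP row was not detectably lower in the arrays labelled KHSRP siRNA. Its level was 5.59 ± 0.03 (SD, n = 3) in them and 5.66 ± 0.08 (SD, n = 3) in the arrays labelled scramble siRNA. The log2 fold change was -0.07 (SE 0.08, limma adjusted p = 0.804, range -0.12 to -0.02 over the alternatives). Such ranges are given for the 24 named genes, none of them called, whose value moved by more than 1.5 times or changed sign in some alternative. On the linear scale this was 95.3% of the scramble level, with a 95% confidence interval from 83.6% to 109%. The exact permutation test gave p = 0.3, where 3 arrays against 3 allow no p below 0.1. The row also carries the annotation of MIR3940, and its mean lay at the 65.6th percentile of the tested genes. The target's level therefore does not check the labels, and the groups are named below by their labels alone. The paralogs FUBP1 and FUBP3, which share the KH-domain architecture, had log2 fold changes of 0.22 (SE 0.14, adjusted p = 0.592) and -0.12 (SE 0.11, adjusted p = 0.757). FUBP1 ran from 0.09 without scramble replicate 1 to 0.33 with the covariate for array medians, and FUBP3 from -0.22 without KHSRP siRNA replicate 2 to -0.03 without replicate 3.

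Metallothionein genes, which encode small metal-binding proteins, made up 6 of the 12 protein-coding genes named for the largest rises in the arrays labelled KHSRP siRNA. MT1F rose 5.95-fold, from 8.39 ± 0.62 to 10.96 ± 0.58 (log2 fold change 2.57, SE 0.37, adjusted p = 0.0473). MT1X rose 5.03-fold, from 11.24 ± 0.11 to 13.57 ± 0.75 (SE 0.33), and MT2A rose from 13.17 ± 0.32 to 15.17 ± 0.65 (SE 0.32). MT1G, MT1B and MT1M rose by 1.46, 1.31 and 1.20 on the log2 scale, with SE of 0.15, 0.20 and 0.12. The scramble mean of MT1M, 4.38, lay under 4.73, the 95th percentile of olfactory receptor genes. Near-identical family members can share probes, so the split between them is uncertain. The other 6 were the apolipoprotein gene APOC1 (log2 fold change 1.45, SE 0.17), the retroelement silencing factor RESF1 (1.39, SE 0.20), the membrane protein gene TM4SF1 (1.37, SE 0.20), the cell cycle regulator RGCC (1.33, SE 0.12), the nuclear phosphoprotein gene NUCKS1 (1.22, SE 0.19) and ANLN, which encodes anillin of the cytokinetic ring (1.16, SE 0.17).

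**Figure D1:**
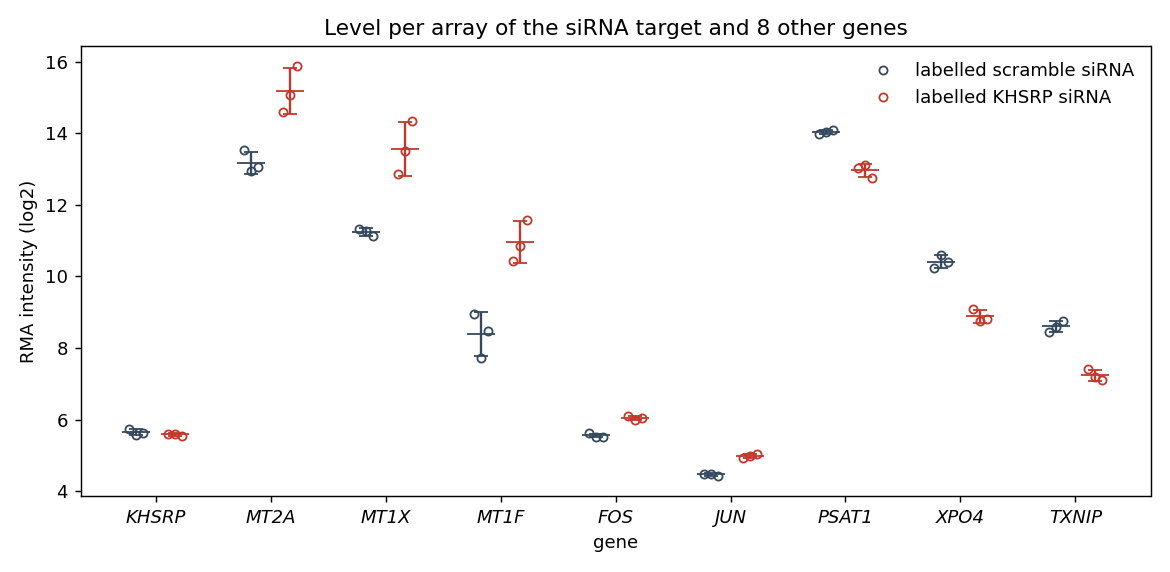
Deposited log2 intensity (vertical axis, labelled RMA intensity) of KHSRP and 8 other genes in each array. Open circles are arrays, horizontal bars are group means and error bars are SD (n = 3), in dark blue for arrays labelled scramble siRNA and in red for arrays labelled KHSRP siRNA. The KHSRP groups overlap (5.66 against 5.59). The groups of the other 8 genes do not, but these were picked among the 170 called genes, all without overlap, so this is no contrast to KHSRP. Of all tested genes 19.4% had groups without overlap, against 10% by chance.

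The largest fall was that of XPO4, a nuclear transport receptor gene, from 10.42 ± 0.18 to 8.88 ± 0.18 in the arrays labelled KHSRP siRNA (log2 fold change -1.53, SE 0.13, adjusted p = 0.0438). TXNIP, which encodes a thioredoxin-binding protein, fell from 8.61 ± 0.15 to 7.24 ± 0.16 (-1.37, SE 0.12). PSAT1, an enzyme gene of serine synthesis, fell from 14.03 ± 0.05 to 12.96 ± 0.19 (-1.08, SE 0.11). MDN1 and RIOK1, which act in the maturation of ribosomal subunits, fell by 1.11 and 1.02 on the log2 scale (SE 0.17 and 0.16). VIPAS39 and VPS33A, with roles in vesicle trafficking, fell by 1.06 and 1.05 (SE 0.17 and 0.12). ERN1, which encodes the endoplasmic reticulum stress sensor IRE1, fell by 1.04 (SE 0.13), and TNFRSF10D, a decoy receptor gene for the ligand TRAIL, fell by 1.10 (SE 0.17). The remaining 3 of the 12 were RCC1L (-1.23, SE 0.15), the mitochondrial dehydrogenase gene ETFDH (-1.16, SE 0.15) and EBLN2 (-1.13, SE 0.17). With the mean of its rows in place of the brightest row, RCC1L was at -0.82.

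Of 22412 tested genes, 170 passed limma's adjusted threshold, 114 higher (67.1%) and 56 lower in the arrays labelled KHSRP siRNA. Of these, 44 differed by at least 2-fold, 32 higher and 12 lower. Rises ran from 0.49 to 3.55 and falls from -0.50 to -1.53. By gene type, 151 were protein-coding (97 higher and 54 lower), 9 were pseudogenes and 7 were small RNA genes, and both of these kinds were higher throughout. All adjusted p-values of these genes lay between 0.0438 and 0.0496, just inside the threshold. At an unadjusted limma p under 0.05 there were 3227 genes, against 1121 expected by chance. Quantile normalization of the table again left 32 calls, 11 higher (34.4%) and 21 lower, and centring on array medians left 0 by limma, with 3111 genes at an unadjusted p under 0.05. Leaving out replicate 2 or 3 of the KHSRP siRNA group, or replicate 2 or 3 of the scramble group, left 0 calls by limma (3081, 2372, 2531 and 2513 genes at an unadjusted p under 0.05), leaving out scramble replicate 1 left 1, and leaving out KHSRP siRNA replicate 1 gave 329. A covariate that separates the 3 arrays with higher medians from the 3 with lower ones left 0 calls by limma, with 3535 genes at an unadjusted p under 0.05. Of the 170 genes, 10 had at least 1 group mean under 4.73, the 95th percentile of olfactory receptor genes, and 4 had both. Fold changes of these genes are approximate, since RMA can compress differences near background, which was not tested on the deposited scale.

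**Figure D2:**
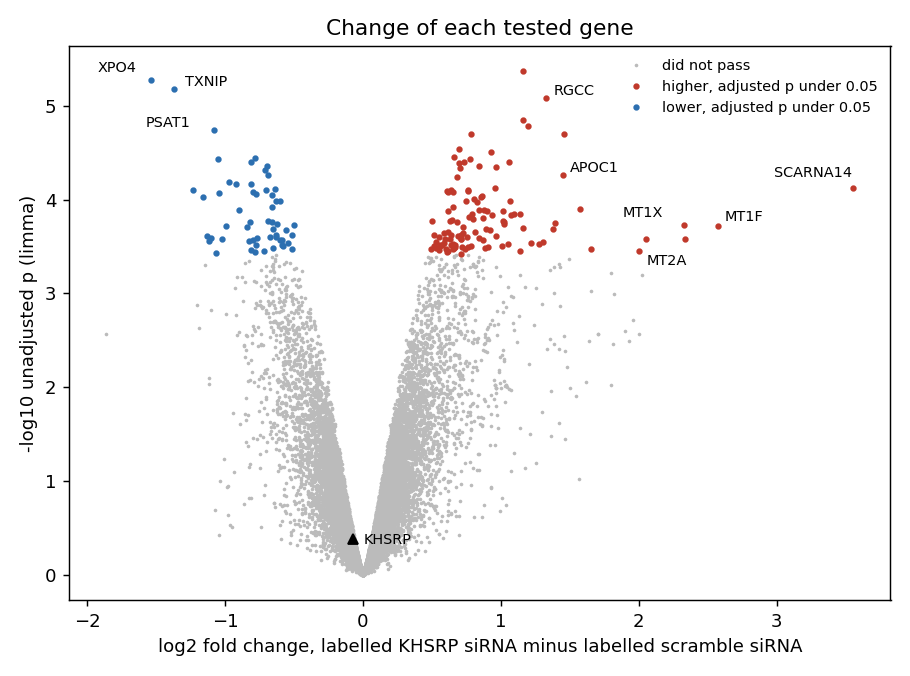
Log2 fold change (horizontal axis, arrays labelled KHSRP siRNA minus arrays labelled scramble siRNA) against -log10 of limma's unadjusted p (vertical axis) for the 22412 tested genes. Red points are the 114 genes called higher, blue points the 56 called lower, grey points the rest, and the black triangle is KHSRP at -0.07.

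Camera called 11 of the 26 gene lists, 9 higher and 2 lower in the arrays labelled KHSRP siRNA. None of the 11 calls held with an estimated correlation, where the smallest adjusted p was 0.322. Camera's preset assumes nearly independent members, and list p-values below are camera's adjusted values at that preset unless the estimated correlation is named. The medians of all 15 lists not called moved by more than 1.5 times or changed sign in some alternative, so their ranges over the alternatives are given. Adjustment over a list alone makes no correction for the 26 lists or for the other genes. Members that passed only there are named as a description and were not called.

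Among AU-rich-element transcripts described as KHSRP targets, the transcription factor genes JUN and FOS rose. JUN went from 4.47 ± 0.03 to 4.99 ± 0.06 (log2 fold change 0.52, SE 0.08, adjusted p = 0.0473) and FOS from 5.56 ± 0.05 to 6.06 ± 0.05 (0.49, SE 0.08, adjusted p = 0.0473). The scramble mean of JUN lay under 4.73, the 95th percentile of olfactory receptor genes, so its fold change is approximate. The other 19 of 21 measured members did not pass, and the same 2 passed adjusted over the list alone. As a whole the list did not pass (median log2 fold change 0.05, adjusted p = 0.205), and its median ran from -0.02 among genes above the median level to 0.11 without KHSRP siRNA replicate 1. Inflammatory AU-rich-element transcripts had 0 of 22 members past the threshold, also 0 adjusted over the list alone (median 0.08, range 0.04 to 0.17, adjusted p = 0.205), with NFKBIA at 0.47 (SE 0.11) and IER3 at 0.26 (SE 0.10). AU-rich-element binding and KH-domain protein genes had 0 of 20 and, adjusted over the list alone, 1, FMR1 at -0.53 (median -0.01, adjusted p = 0.688). That median ran from -0.11 without KHSRP siRNA replicate 2 to 0.05 with the covariate for array medians, and was above 0 in 4 of 15 alternatives, so its sign is not settled. The abundant members YBX1 and PCBP2 had values of -0.01 (SE 0.10, range -0.10 to 0.08) and 0.16 (SE 0.08).

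The mRNA decay and microRNA processing list was lower (median log2 fold change -0.11, adjusted p = 0.00482, and adjusted p = 0.322 with an estimated correlation). Its median was -0.07 without KHSRP siRNA replicate 3 and -0.05 without scramble replicate 2. None of its 19 measured members passed over all genes, and 3 did adjusted over the list alone. These were the microRNA precursor exporter XPO5 (-0.83, SE 0.14), the nuclease DICER1 (-0.66, SE 0.11) and the deadenylase scaffold CNOT1 (-0.55, SE 0.13). DDX17, its brightest member, was at -0.11 (SE 0.15, range -0.25 to 0.03). Of 22 measured let-7 targets none passed, and adjusted over the list alone 1 did, again DICER1 (list median -0.04, range -0.08 to -0.002, adjusted p = 0.264). MYC, in that list, was at -0.05 (SE 0.09, range -0.11 to 0.01).

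Cell cycle lists went in different directions. G2/M and mitosis genes were higher (median 0.10, adjusted p = 0.0185, and adjusted p = 0.322 with an estimated correlation). Of 27 measured, ANLN passed over all genes, and 6 did adjusted over the list alone, among them the mitotic kinase gene PLK1 (0.72, SE 0.12), the ubiquitin-conjugating enzyme gene UBE2C (0.62, SE 0.13) and the kinetochore motor gene CENPE (0.57, SE 0.10). The brighter members TOP2A and TPX2 were at 0.10 (SE 0.08, range 0.04 to 0.14) and -0.29 (SE 0.11). The 8 measured of 20 replication-dependent histone genes (the other 12 stood on rows with several symbols) were all fitted above 0 and higher as a list (median 0.49, adjusted p = 0.00249, and adjusted p = 0.322 with an estimated correlation). None passed singly, over all genes or adjusted over the list alone, with H1-2 at 1.06 (SE 0.31) and H2BC12 at 0.52 (SE 0.20). G1/S and DNA replication genes were lower (median -0.08, adjusted p = 0.0154, and adjusted p = 0.517 with an estimated correlation). None of 28 passed over all genes or adjusted over the list alone, with MCM6 at -0.44 (SE 0.12) and TYMS at -0.04 (SE 0.17, range -0.21 to 0.13). The G1/S call was lost without KHSRP siRNA replicate 2 (adjusted p = 0.139, median -0.02) or scramble replicate 2 (0.125, median -0.01), and its median was -0.20 without KHSRP siRNA replicate 1. The G2/M call was lost without KHSRP siRNA replicate 1 (0.0655), replicate 2 (0.0512) or scramble replicate 2 (0.0668), among genes above the median level (0.0780) and with array weights (0.0569). Its median was 0.16 without KHSRP siRNA replicate 3 and 0.07 after quantile normalization again.

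Among biosynthetic and energy genes, cytosolic ribosomal protein genes were higher by a small amount (median 0.24, adjusted p = 2.01e-05, and adjusted p = 0.417 with an estimated correlation), with a median of 0.16 without scramble replicate 2. Of the 29 written, 11 were not measured, 6 of them on rows with several symbols. Of the 18 measured members 17 were fitted above 0 and 0 passed singly, also 0 adjusted over the list alone, with RPS16 at 0.20 (SE 0.13, range 0.07 to 0.29) and RPL27 at 0.26 (SE 0.13, range 0.12 to 0.38). Cholesterol biosynthesis genes were higher (median 0.21, adjusted p = 5.07e-04, and adjusted p = 0.322 with an estimated correlation). Of 18 measured, the sterol oxidase gene MSMO1 rose (0.65, SE 0.09, adjusted p = 0.0473), and 6 passed adjusted over the list alone, among them HMGCS1 (0.71, SE 0.16), SC5D (0.62, SE 0.12) and NSDHL (0.61, SE 0.12). CYP51A1 and SQLE were at 0.21 (SE 0.11, range 0.14 to 0.31) and 0.10 (SE 0.08). Oxidative phosphorylation genes were higher (median 0.29, adjusted p = 0.0132, and adjusted p = 0.443 with an estimated correlation). Of 20 measured, UQCRC2 of complex III rose (0.53, SE 0.08, adjusted p = 0.0473). Adjusted over the list alone 9 were higher, among them NDUFB3 (0.98, SE 0.21), COX5A (0.65, SE 0.17) and NDUFA1 (0.45, SE 0.15), and 2 were lower, NDUFS1 (-0.48, SE 0.09) and ATP5F1B (-0.23, SE 0.08). Over all genes limma's adjusted p was 0.213 for NDUFA1 and 0.230 for ATP5F1B. The oxidative phosphorylation call was lost without KHSRP siRNA replicate 1 (camera adjusted p = 0.0718).

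Hypoxia and glycolysis genes were higher as a list (median 0.09, adjusted p = 0.0371, and adjusted p = 0.417 with an estimated correlation). Of 24 measured, ANKRD37 (0.76, SE 0.12) and EGLN3 (0.56, SE 0.09), both known as hypoxia-induced genes, rose at an adjusted p of 0.0473. The scramble mean of EGLN3, 4.51, lay under the 4.73 named above. Adjusted over the list alone the glucose transporter gene SLC2A1 was also higher (1.46, SE 0.33) and the hexokinase gene HK2 lower (-0.99, SE 0.20). The list call was lost without KHSRP siRNA replicate 2 (adjusted p = 0.241), KHSRP siRNA replicate 3 (0.105) or scramble replicate 1 (0.212). It was also lost after quantile normalization again (0.0749), among genes above the median level (0.0969), with an intensity trend and robust prior (0.0586), with array weights (0.0639) and with the mean of a gene's rows (0.0775). The median ran from 0.06 without scramble replicate 1 to 0.14 without KHSRP siRNA replicate 1, and was 0.05 after quantile normalization again.

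Colonocyte differentiation markers were higher (median 0.09, or 0.19 among genes above the median level, adjusted p = 0.0174, and adjusted p = 0.322 with an estimated correlation). None of 24 passed over all genes and 3 did adjusted over the list alone, all of them keratin genes of simple epithelia: KRT8 (0.58, SE 0.11), KRT19 (0.55, SE 0.14) and KRT18 (0.49, SE 0.09). Mesenchymal transition genes were also higher (median 0.26, adjusted p = 0.0185, and adjusted p = 0.417 with an estimated correlation). None of 17 passed and 1 did adjusted over the list alone, the matrix protein gene TGFBI (0.75, SE 0.15), with S100A4 at 0.45 (SE 0.12) and AXL at 0.37 (SE 0.20, range 0.21 to 0.62). The colonocyte call was lost without KHSRP siRNA replicate 1 (adjusted p = 0.0549) or scramble replicate 1 (0.0532), and the mesenchymal call without KHSRP siRNA replicate 2 (0.0935) or scramble replicate 3 (0.0590). Wnt and beta-catenin target genes did not pass as a list (median 0.13, adjusted p = 0.764), and their median ran from 0.02 to 0.11 when arrays were left out. None of 22 passed, and adjusted over the list alone SOX9 (0.67, SE 0.17) and CD44 (0.48, SE 0.11) were higher and NKD1 (-0.65, SE 0.11) was lower, with AXIN2 at -0.28 (SE 0.12).

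Genes of secreted chemokines, cytokines and growth factors were higher (median 0.15, or 0.10 without scramble replicate 3, adjusted p = 0.0132, and adjusted p = 0.322 with an estimated correlation). None of 29 passed, and adjusted over the list alone 2 were higher, the cytokine gene MIF (0.84, SE 0.15) and the growth factor gene PDGFA (0.51, SE 0.08). CXCL16 was at -0.54 (SE 0.15). Among 22 angiogenesis regulators the protease inhibitor gene TIMP1 rose, from 5.81 ± 0.12 to 6.44 ± 0.09 (0.63, SE 0.10, adjusted p = 0.0473). Adjusted over the list alone the receptor gene NRP1 was also past the threshold, at -0.54 (SE 0.12), and JAG1 was at -0.13 (SE 0.12, range -0.23 to -0.03). That list did not pass (median 0.10, range 0.06 to 0.12, adjusted p = 0.0860). Matrix protease and matrix genes did not pass either (0 of 25, also 0 adjusted over the list alone, adjusted p = 0.796). Their median was 0.02, or -0.0003 after quantile normalization again and -0.005 after median centring, with a range from -0.02 to 0.05. ADAM17 and ADAM10 were at -0.36 (SE 0.17, range -0.48 to -0.18) and 0.11 (SE 0.10, range 0.04 to 0.19).

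In the integrated stress and unfolded protein response list, PSAT1 and the lipoprotein receptor gene VLDLR (-0.82, SE 0.12, adjusted p = 0.0473) fell, the same 2 adjusted over the list alone, and 21 of 23 members did not pass. The list did not pass (median -0.04, adjusted p = 0.0561, and adjusted p = 0.322 with an estimated correlation). It passed after quantile normalization again (adjusted p = 0.0273) and without KHSRP siRNA replicate 2 (0.0438), KHSRP siRNA replicate 3 (0.0274) or scramble replicate 1 (0.0269). Its median ran from -0.09 after quantile normalization again to -0.007 without scramble replicate 3. Of 20 p53 and CDK-inhibitor genes none passed, and adjusted over the list alone 2 were lower, MDM2 (-0.68, SE 0.14) and TNFRSF10B (-0.48, SE 0.10). BAX was at -0.14 (SE 0.12, range -0.26 to -0.07), and the list median was 0.12 (range 0.05 to 0.17, adjusted p = 0.855). Of 20 apoptosis regulators none passed, and adjusted over the list alone the proapoptotic gene PMAIP1 was higher (0.72, SE 0.15), with BIRC2 at 0.43 (SE 0.17, range 0.28 to 0.61) and a list median of 0.06 (range 0.02 to 0.13, adjusted p = 0.193). None of 25 interferon-stimulated genes passed, also 0 adjusted over the list alone (median -0.02, adjusted p = 0.305), with IFIH1 at -0.28 (SE 0.12) and OAS1 at 0.18 (SE 0.10, range 0.11 to 0.23). That median was 0.04 without KHSRP siRNA replicate 2, 0.03 without scramble replicate 1 and -0.06 without KHSRP siRNA replicate 1, within a range from -0.08 to 0.04.

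Splicing genes did not pass as a list (median -0.09, adjusted p = 0.0793, and adjusted p = 0.574 with an estimated correlation). They passed after quantile normalization again (adjusted p = 0.0352), with array weights (0.0203) and without KHSRP siRNA replicate 2 (0.00470) or scramble replicate 1 (0.0242). Their median ran from -0.15 without KHSRP siRNA replicate 2 to -0.01 with the covariate for array medians. None of their 28 measured members passed, also 0 adjusted over the list alone, with HNRNPU at -0.16 (SE 0.10, range -0.22 to -0.08) and HNRNPA2B1 at 0.02 (SE 0.11, range -0.06 to 0.10), or -0.02 after quantile normalization again. Of 22 lysosome and autophagy genes none passed, and adjusted over the list alone the lysosomal membrane protein gene LAMP2 was higher (0.84, SE 0.14), with NPC1 at -0.07 (SE 0.18, range -0.22 to 0.13) and a list median of 0.05 (range 0.007 to 0.10, adjusted p = 0.764). Markers of fibroblasts, endothelium and leukocytes, included as a check for other cells, had 0 of 22 members past the threshold, also 0 adjusted over the list alone (median -0.0003, range -0.02 to 0.03, adjusted p = 0.796), with ACTA2 at 0.24 (SE 0.11, range 0.14 to 0.31) and CD68 at -0.02 (SE 0.09, range -0.08 to 0.03). The 13 measured housekeeping genes had 0 past it, also 0 adjusted over the list alone (adjusted p = 0.801), with TUBB at 0.26 (SE 0.10, range 0.17 to 0.32) and GAPDH at 0.24 (SE 0.09). The housekeeping median was 0.03, and -0.01 after quantile normalization again, with a range from -0.03 to 0.05.

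**Figure D3:**
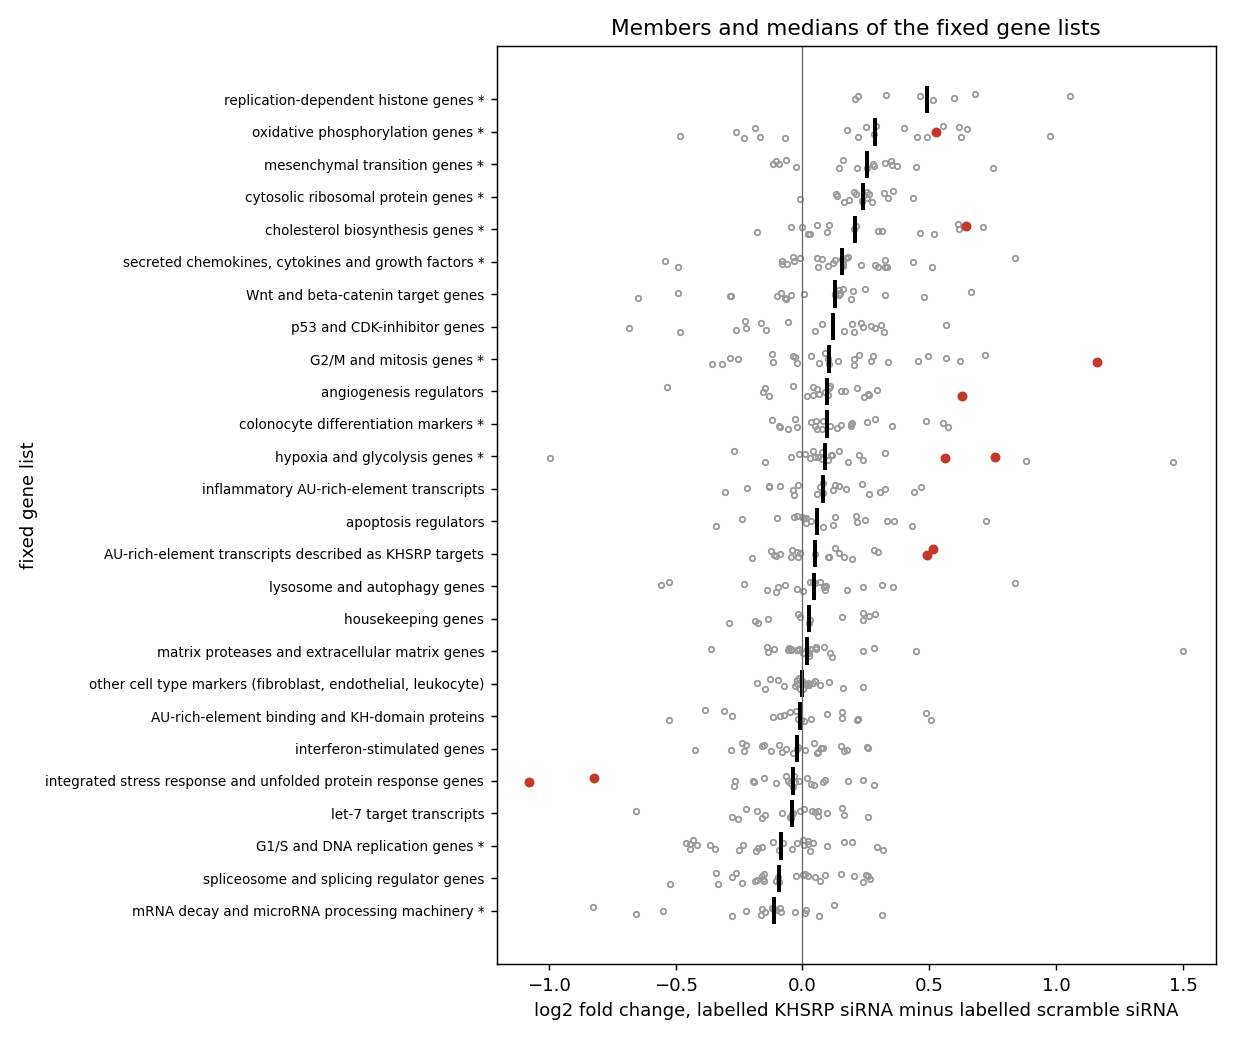
Log2 fold changes (horizontal axis, arrays labelled KHSRP siRNA minus arrays labelled scramble siRNA) of the measured members of the 26 fixed lists (vertical axis). Filled red circles passed the adjusted threshold over all genes, open grey circles did not, black bars are list medians, and an asterisk marks the 11 lists called by camera at the preset correlation. Medians run from -0.11 in the mRNA decay and microRNA processing list to 0.49 in the histone list.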

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

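The inclusion of rows with several symbols, the block joined to an estimated correlation and the covariate for higher array medians were chosen after seeing the data. In the 15 alternatives that refitted the named genes, all of the 170 called genes that were measured (165 with the filter on dim genes) kept an unadjusted p under 0.05. Their groups did not overlap, so leaving out an array could not turn a sign. The genes were also picked for small p-values on these same arrays. So neither their signs nor an unadjusted p under 0.05 measure how stable these calls are. Their adjusted p-values in the main setting lay between 0.0438 and 0.0496, close to the threshold. KHSRP stayed uncalled in the same 15, at -0.12 to -0.02 (adjusted p 0.574 to 0.939).

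Calls, with those of at least 2-fold second, numbered 32 and 12 after quantile normalization again, 0 and 0 after median centring (3111 at an unadjusted p under 0.05), 0 and 0 with an intensity trend and robust prior (3097), 0 and 0 with the covariate for higher array medians (3535) and 0 and 0 over all rows of the table (7130). They numbered 433 and 69 among genes above the median level, where fewer genes were tested, and 704 and 99 with array weights. The unmoderated model called 1, an adjusted p under 0.10 gave 657, one under 0.01 gave 0, and an unadjusted p under 0.05 with a 1.5-fold change gave 732. The mean of a gene's rows and the inclusion of rows with several symbols each gave 173. Leaving out arrays gave 0 to 329 calls, 0 to 97 of at least 2-fold and 8 to 11 lists. Apart from the smaller number of genes or arrays, the cause was not tested.

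Lists called numbered 0 with an estimated correlation and 7 by fry, which makes no comparison with other genes. Of these, 4 (cholesterol, secreted factor, colonocyte and G2/M) were among the 11, 3 (integrated stress, angiogenesis and apoptosis) were not, and fry left out the other 7 of the 11. Counts lay between 8 and 12 in the settings that kept camera's preset. Ribosomal protein, cholesterol, histone and mRNA decay lists were called in all of the latter. The covariate for higher array medians gave 11 lists, or 0 with an estimated correlation. The secreted factor list was not called among genes above the median level (adjusted p = 0.0819).

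With the replicate number as a block, 1 gene was called, lower by at least 2-fold, and not among the 170, while 11 lists were called, or 0 with an estimated correlation. Deviations of same-numbered arrays from their group means correlated at 0.164, 0.059 and -0.076, so the numbers were not taken to pair the arrays, and only number 1 correlated best with its own number.

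Among named genes, values that changed sign belonged to 7 uncalled genes. Medians of 6 lists, none of them called, also changed sign in some alternative (AU-rich-element targets, AU-rich-element binding proteins, interferon-stimulated genes, other cell types, matrix and housekeeping). HNRNPA2B1 was at -0.0181 after quantile normalization again, -0.00015 after median centring and -0.0446 with array weights, and NPC1 at 0.00259 with array weights. YBX1 was at 0.0217 with the covariate for higher array medians. Leaving out arrays gave -0.0596 to 0.0977 for HNRNPA2B1, -0.221 to 0.135 for NPC1, -0.246 to 0.0264 for DDX17, -0.0803 to 0.0289 for CD68, -0.211 to 0.127 for TYMS, -0.0679 to 0.0801 for YBX1 and -0.107 to 0.0149 for MYC. The cause was not tested. Tests of AU-rich elements and let-7 sites in 3' untranslated regions were not run. Low levels may limit the fold changes that the deposited values can show, and KHSRP lay at 5.59 against a median of 4.76 over all genes.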

Other observations

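The tests of exchanged arrays, of correlation between members, of metallothioneins and of other splits for gene counts were chosen only after the result was seen, as were the gene families below, which were drawn up once the called genes were known. Genes of cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, were mostly lower in the arrays labelled KHSRP siRNA. IARS1 fell from 12.80 ± 0.20 to 11.83 ± 0.08 (SD, n = 3; log2 fold change -0.97, SE 0.12, limma adjusted p = 0.0438), and LARS1 and SARS1 fell by 0.81 and 0.77 (SE 0.13 and 0.12). XPOT, which encodes the tRNA exporter, fell by 0.90 (SE 0.12, adjusted p = 0.0473). Of 19 measured cytosolic synthetase genes 17 were fitted below 0 and 3 passed, with a median of -0.26, and -0.27 and -0.29 under the 2 other scalings. The 16 measured mitochondrial synthetase genes had a median of 0.03 and 0 passed. Genes of serine, asparagine and amino acid supply had a median of -0.19, with 13 of 15 fitted below 0 and PSAT1 called. Endoplasmic reticulum chaperone genes had a median of -0.05, with 0 of 13 called. A candidate explanation is a shared fall of the cytosolic family. Camera with an estimated correlation gave p = 0.0706 for it and 0.406 for the mitochondrial family, and adjusted over the 10 families the first was 0.176, so this stays open. Camera's preset gave an adjusted p of 8.45e-10 for the cytosolic family. That preset assumes nearly independent members, whereas the correlation estimated for this family was 0.383. The called genes IARS1, LARS1 and SARS1, known before the family was drawn up, are also among its members. So the preset value decides nothing.

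Small RNA genes were among the largest rises. SCARNA14 rose from 7.81 ± 0.96 to 11.36 ± 0.35 (log2 fold change 3.55, SE 0.44), SNORA79 by 2.34 (SE 0.35), SNORD13 by 1.66 (SE 0.26), RNU5F-1 by 1.57 (SE 0.21) and the microRNA gene MIR221 by 1.28 (SE 0.20), at adjusted p-values between 0.0438 and 0.0477. The near-identical copies SNAR-C3 and SNAR-C4 were also called, but their levels lay under the olfactory receptor median of 3.72, so no fold change is given. Of 24 measured snRNA genes 22 were fitted above 0 (median 0.67, and 0.66 and 0.65 under the 2 other scalings), while 240 snoRNA genes had a median of 0.03, and 1041 microRNA genes 0.01. The hypothesis that small RNA classes may have risen as a whole was tested by camera with an estimated correlation, with p = 0.0454 for snRNA and 0.664 for snoRNA genes. The first was 0.176 adjusted over the 10 families and 0.0527 without the 9 SNAR genes, and the called genes that prompted the test are among its members, so it decides nothing. As broader classes, 1937 lncRNA genes had a median of 0.01 and 17155 protein-coding genes one of 0.02.

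The KHSRP row was not detectably lower in the arrays labelled KHSRP siRNA. Arrays exchanged between the groups are argued against by Pearson correlations and, over the tested genes, by Spearman correlations. By these, 0 arrays of either group correlated better with the other group than with their own, and an exchange needs arrays of both groups. By Spearman over all rows 0 arrays labelled KHSRP siRNA did, but 2 scramble arrays did (replicate 2, 0.948 against 0.951, and replicate 3, 0.950 against 0.953). KHSRP siRNA replicate 2 lay close to these 2 (0.9515 and 0.9546, against 0.9487 and 0.9535 within its group), so that measure decides nothing. An exchange of all 6 labels would not show in these correlations. The row itself ran from 5.556 to 5.753 over the 6 arrays, and its 95% interval reached 109% of the scramble level. Unless the row is at background, this argues against an exchange of some or all labels that hid a marked fall. A row near background may hide a fall. Of 359 olfactory receptor genes, which a colon line is not thought to express, 3 lay above the row's mean and 99.16% did not. That share is past the 99% first set to exclude background. Its exact 95% interval ran from 97.6% to 99.8%, and the stricter bound asked for all of the interval above 99%. With 359 genes no level of the row could have met that bound. The interval therefore decides nothing, and background stays open. An siRNA that did not lower the transcript, or had recovered by 48 h, stays open and was not tested.

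Ribosomal protein genes (17 of 18 fitted above 0) and oxidative phosphorylation genes (14 of 20) were mostly higher, with a joint median of 0.25 over 38 members. An intensity trend left by the normalization is argued against as the whole of the rise, since genes of like level did not shift so far. Medians of 10000 random lists matched on mean level centred on 0.03, with 5th to 95th percentiles from -0.06 to 0.12. The joint median lay at their 99.95th percentile. That rank is no measure of chance, since the 2 lists were picked as called and their members correlate (0.547 and 0.25), unlike random genes. Quantile normalization again lowered the 2 medians to 0.20 and 0.24, so a part from scaling is not excluded. An array-wide factor that differs between replicates would give a residual correlation between members, which was 0.25 in the list with the smaller value. Both calls were lost when the correlation was estimated, as were all 11 list calls, so that loss adds nothing. Members that vary together for any other reason would give the same correlation, so an array-wide factor stays possible and is not shown. Both lists had higher means in each array labelled KHSRP siRNA than in any labelled scramble siRNA. A difference made by the siRNA stays open, untested beyond this comparison, and technical differences between the groups other than these were not tested.

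All 11 measured metallothionein genes were fitted higher, 6 of them called, with a median of 1.38 (1.33 and 1.36 under the 2 other scalings, and 1.25 to 1.52 leaving out arrays). An intensity trend is argued against, since genes of like level did not shift so far. Medians of 10000 lists matched on mean level ran from -0.11 to 0.17 (5th to 95th percentile), and the highest reached 0.43. The family was picked for its rises, so its rank above 100% of these lists adds nothing. Camera with an estimated correlation gave p = 0.0360, or 0.176 adjusted over the 10 families, and shared probes could spread the rise of a few genes over the family. The pair farthest apart in standard errors, MT1X and MT1L, differed by 1.32 on the log2 scale and 5.735 standard errors, beyond the bound of 4 written for it, but that bound was wrong for the largest of 55 pairs with 4 degrees of freedom, where p times the number of pairs is 0.252. So how many members rose cannot be told apart from shared probes, and a response of the cells to the siRNA, or to a difference in culture between the groups, remains a hypothesis.

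Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split gave 170 called genes, 44 of at least 2-fold and 11 lists, and the highest of the other splits gave 0, 0 and 6. For each of these 1 split, the real one, gave a result as large. None of the other splits called a gene by limma, with 542 to 2199 genes at an unadjusted p under 0.05. The 2199 and the 6 lists came from the split of KHSRP siRNA replicates 1 and 3 and scramble replicate 1, the 3 arrays with the higher medians, against the others. Within each of these classes, compared without a test, 10 of the 11 called lists kept their sign, and the metallothionein median was 1.34 and 1.32. The groups did not overlap in any metallothionein gene, nor in the per-array means of the called lists other than G1/S. So these signs could hardly turn, and they are no measure of stability.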
